A study of Mus musculus with 24 samples.

How the data were processed

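The deposited values are intensity signals of 45101 probe sets on 24 arrays, made by the authors with MAS5 per the submitters' processing notes, which give no version. A second deposited table holds, for each probe set and gradient, the share of the signal in the polysomal fraction, polysomal over polysomal plus subpolysomal, per the file headers. Per the labels, immortalized mouse erythroblasts grew in serum-free medium with Epo, SCF and Dex, were harvested in the presence of cycloheximide (3 days after lentiviral delivery where a construct was given), and 7 µg of RNA went into each labelling. The labels call the 3 gradients of each group biological replicates. The description of Rps19 replicate 3 alone holds the word puro, and its meaning is not given.

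The signals are linear, and the mean of each array after trimming 2% at each end lies between 499.77 and 500, so they were used as deposited. The deposited shares were recomputed from the signals with a largest difference of 7.1e-10. In 2 probe sets a value is missing on 6 arrays. Signals were taken as log2 of the value plus 7.8516, that is 0.1 of the median signal of 78.516. Of the probe sets, 34958 have 1 gene symbol in the annotation used (34754 of them found by gene ID), 932 have several and 9211 have none. Probe sets below the median of the mean log2 signal (50%) and control probe sets were removed, and the brightest probe set of each gene was kept, which left 11035 genes. Correlations between arrays of log2 signals run from 0.848 to 0.984. No array was left out. The precision that 3 gradients give was checked on simulated data. With 100 changed genes among 11035, a log2 change of 1 was called in 34% to 50% of genes in the comparisons of groups and in 69% in the comparison of the pools. A log2 change of 0.5 was called in 0% to 3% and in 21%. At most 5 unchanged genes were called.

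Tests were run with R 4.3.3 and limma 3.58.1. Each gradient gives 1 recruitment value (log2 polysomal minus log2 subpolysomal signal) and 1 level value (mean of both) per gene. Linear models with the shRNA group as the only factor were fitted to all 12 gradients, with moderated t statistics and p adjusted by Benjamini-Hochberg over all genes at a threshold of 0.05. Comparisons were the Rps19 and the Rpl11 shRNA against the control construct, the shRNAs against each other, the control construct against untransduced cells, and the pools of untransduced cells against each other. Level stands in for mRNA amount, since no unfractionated RNA was measured. Correlations of residuals show that the 2 arrays of a gradient belong together (12 of 12 above 0.1, from 0.156 to 0.601). In recruitment the replicate number does not pair gradients across groups (0 of 18 above 0.1, from −0.126 to 0.0871). In level 7 of 18 lie above 0.1 (from −0.332 to 0.528), among them all 3 of the control construct with the Rps19 shRNA (0.528, 0.294 and 0.21). No block was fitted in the main models, and lists in the level of this comparison were also tested with the replicate number or the set of gradients in the model.

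Comparisons, gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. Of 31 fixed lists 27 have at least 3 tested genes. They cover ribosomal proteins of each subunit, other TOP mRNAs, initiation factors, mitochondrial ribosomal proteins, ribosome biogenesis, erythroid membrane and haemoglobin, erythroid regulators, haem and iron, reported internal ribosome entry sites, p53 targets, the integrated stress response, cytosolic chaperones, oxidative phosphorylation, proteasome, DNA replication, mitosis, apoptosis, cholesterol synthesis, interferon response, untranslated RNAs and 6 sets of cell type markers. Lists were tested with camera at its preset correlation of 0.01 and again with the correlation estimated from the data, and their p were adjusted over the lists. Genes over the list alone means Benjamini-Hochberg within the list. Medians of lists were also compared with those of 10000 random lists drawn from the 40 genes nearest in mean signal to each member. A probe set counts as near the ceiling when its signal is on average at least 0.4 of the highest signal of the array (85 genes).

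Named genes follow a rule. Rps19, Rpl11 and Bag1 are always named. Each comparison against the control construct names the 10 largest increases and decreases past the threshold whose 3 values per group do not overlap, and the other comparisons name 5. Where fewer than 5 pass, those with the smallest p are named as not past it. Each list adds up to 4 members past the threshold with the smallest p, or 2 members where none passed. Genes called with both shRNAs were picked from their full table after the values were seen. Not all genes the rule allows are printed, and the text leaves out clones and predicted transcripts. Correlation and overlap of the shRNA effects were set against 100 simulated data sets without effects and with the shared control.

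Alternatives tried were unpaired arrays, the replicate number as a block, fits to only the groups compared, median scaling, quantile normalization over all arrays and within each fraction, pseudocounts of 1 and of 39.258, no filter and a filter removing 66.7% of probe sets, all probe sets, a variance prior with trend and robust, a threshold of 0.1, the deposited shares, the log2 of the summed signal and leaving out each gradient. Added after the data were seen were the removal of a lowess trend over brightness (span 0.2), leaving out genes near the ceiling, 2 sets of gradients as a factor, the larger set alone, Rpl11 replicates 2 and 3 left out, brightness-matched lists and the 2 ways to pair gradients for lists in the level of Rps19 against the control construct, and gene lists and short proteins against untransduced cells.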

Results

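Rps19 and Rpl11 encode proteins of the small and the large ribosomal subunit, and an inherited defect in either gene causes Diamond-Blackfan anaemia. The series measures which mRNAs of mouse erythroblasts sit on polysomes when either protein runs short. Erythroblasts were left untransduced or received a control construct, an Rps19 shRNA or an Rpl11 shRNA, and 3 cultures per group were lysed, those with a construct 3 days after its delivery. Each of the 12 lysates was split on a sucrose gradient into a polysomal and a subpolysomal RNA pool, and each pool has its own array. Recruitment is log2 polysomal minus log2 subpolysomal signal, and level their mean. Genes counted as higher or lower passed the threshold unless said otherwise. Changes are differences of group means (n = 3 gradients per group) with their standard error (SE), and adjusted p values come from limma over 11035 genes. Every array is scaled to the same mean, so a shift of all mRNA into or out of polysomes leaves no trace in these values.

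Both shRNAs lowered the mRNA of their own target. Rps19 fell by 1.53 (2.88-fold, SE 0.16, adjusted p = 0.00369), from a level of 15.37 ± 0.05 (mean ± SD) with the control construct to 13.84 ± 0.22. Rpl11 fell by 2.66 (6.32-fold, SE 0.25, adjusted p = 0.0011), from 15.23 ± 0.13 to 12.57 ± 0.53. In signal units, Rps19 went from 25800 ± 1270 to 9350 ± 1300 in the polysomal and from 69800 ± 5110 to 23500 ± 3690 in the subpolysomal pool. Rpl11 went from 27500 ± 1320 to 4860 ± 1590 and from 54200 ± 7150 to 8300 ± 2920 in the same pools. In the cells with the control construct these signals lie at 0.594 to 0.73 (Rps19) and 0.528 to 0.704 (Rpl11) of the highest signal of the array, near the ceiling, so both falls are lower bounds if the signal flattens. The Rpl11 shRNA also lowered Rps19 (−0.57, SE 0.16, adjusted p = 0.0272), while Rpl11 stood at −0.33 (SE 0.25, adjusted p = 0.587) with the Rps19 shRNA. The recruitment of Rps19 differed by 0.10 (SE 0.18, adjusted p = 0.849) under its own shRNA and by 0.07 (SE 0.18, adjusted p = 0.87) under the Rpl11 shRNA. For Rpl11 these values were 0.21 (SE 0.16, adjusted p = 0.501) under its own shRNA and 0.55 (SE 0.16, adjusted p = 0.136) under the Rps19 shRNA. With all arrays quantile normalized, recruitment under the own shRNA differs by −0.93 for Rps19 and by −0.92 for Rpl11, so it is not settled here. Each target has another, dim probe set shared with a second gene symbol, which read −0.61 (SE 0.28, adjusted p = 0.143) for Rpl11 and 0.16 (SE 0.26, adjusted p = 0.825) for Rps19.

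**Figure D1:**
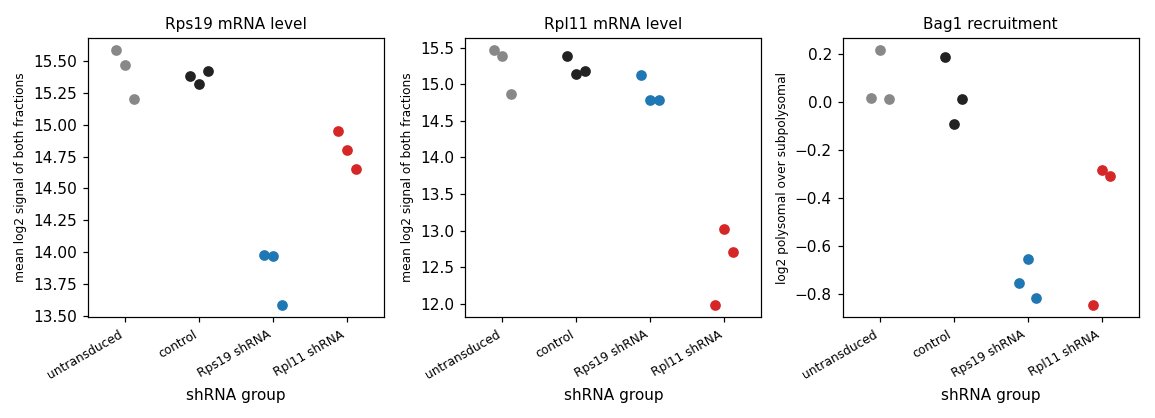
Level of Rps19 and Rpl11 and recruitment of Bag1 in each of the 12 gradients, by shRNA group. Against the control construct Rps19 changed by −1.53 and Rpl11 by −2.66 under their own shRNA, and the recruitment of Bag1 differed by −0.78 and −0.51.

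In untransduced cells all large- and small-subunit ribosomal protein mRNAs were lower on polysomes (22 of 22 and 20 of 21 past the threshold). Their median log2 ratios were −1.49 and −1.58. Other mRNAs with a 5' terminal oligopyrimidine (TOP) tract, through which growth signals set translation, followed at −1.58. All 19 were lower, 18 past the threshold. Initiation factors had a median of −0.25 (4 higher and 14 lower of 30, camera adjusted p = 0.183). Rpsa, Rps18, Fau, Rpl4, Rpl8 and Rpl13a stood at −2.10 (SE 0.11), −1.53 (SE 0.10), −1.61 (SE 0.11), −1.65 (SE 0.10), −1.55 (SE 0.10) and −1.69 (SE 0.11), next to −1.64 (SE 0.13) for Rps19. Rpl11 was 2.30-fold lower in the polysomal pool, whereas Bag1 was even at 0.08 (SE 0.12, adjusted p = 0.613). Among the other TOP mRNAs, the initiation factor subunit Eif3h read −2.22 (SE 0.11), the poly(A)-binding protein Pabpc1 −1.96 (SE 0.10), the elongation factor Eef2 −1.88 (SE 0.10) and the RNA-binding protein Ybx1 −2.24 (SE 0.15). Adjusted p for these genes is at most 4.44e-05, Bag1 aside. In camera the 3 lists reached adjusted p = 7.71e-16 (small subunit), 1.47e-16 (large subunit) and 4.87e-14 (TOP), and adjusted p = 0.265, 0.265 and 0.234 with an estimated correlation. Of these genes 18 of 21 small-subunit, 17 of 22 large-subunit and 8 of 19 TOP mRNAs lie at or above 0.4 of the highest signal of the array. That highest signal is itself lower on polysomal arrays (33398 to 44539, n = 9) than on subpolysomal arrays (74690 to 144500, n = 9).

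Nuclear and untranslated RNAs gave the other large group on the subpolysomal side. The paraspeckle RNA Neat1 read −3.16 (SE 0.12, adjusted p = 5.98e-07), the nuclear RNA Malat1 −2.19 (SE 0.15) and the snoRNA host transcripts Snhg3, Snhg8 and Snhg1 −4.10 (SE 0.50), −1.70 (SE 0.18) and −1.44 (SE 0.17). As a list, 10 of 13 such RNAs were lower and 1, Kcnq1ot1, was higher at 2.37 (SE 0.32, adjusted p = 0.000316), with a median of −1.70 (camera adjusted p = 0.000125, or 0.234 with an estimated correlation). The lowest ratios of all genes also include Mir1949 at −3.88 (SE 0.72), Zbed6 at −3.36 (SE 0.23) and Rab26os at −3.29 (SE 0.44). The highest belong to the DNA end-joining factor Aplf (2.83, SE 0.30), the Golgi-transport regulator Preb (2.61, SE 0.27), the choline transporter Slc44a2 (2.54, SE 0.24) and Cd200r4 (2.35, SE 0.61).

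Erythroid lists had camera adjusted p of 0.293 or more. Of 21 membrane genes 2 were higher and 8 lower. Of 25 haem and iron genes these were 3 and 8, and of 30 regulators 4 and 5. Alas2, the first enzyme of haem synthesis, read −2.12 (SE 0.18, adjusted p = 2.29e-05), and the ferritin chain Fth1 −1.85 (SE 0.14, adjusted p = 1.22e-05). The transferrin receptor Tfrc stood at −1.26 (SE 0.18) and Slc25a39 at −1.10 (SE 0.12). Gypc (0.92, SE 0.12), Flvcr1 (0.92, SE 0.13) and Tal1 (0.67, SE 0.15) were on the polysomal side. Mitochondrial ribosomal protein mRNAs were polysomal, with 36 of 76 higher, 5 lower and a median of 0.31 (camera adjusted p = 8.86e-06, or 0.306 with an estimated correlation). Mrps28 read 1.24 (SE 0.12), Mrps14 1.09 (SE 0.09), Mrpl2 1.07 (SE 0.13) and Mrps12 0.93 (SE 0.10). Apoptosis regulators had a median of 0.20 (5 of 22 higher, camera adjusted p = 0.0445, or 0.234 with an estimated correlation), with Bid at 0.75 (SE 0.11) and Diablo at 0.63 (SE 0.11). The mitochondrial and apoptosis medians lie inside the brightness-matched ranges (0.0329 to 0.35 and −0.288 to 0.287). Ribosome biogenesis mRNAs leaned the other way (median −0.28, 25 of 59 lower, 6 higher, camera adjusted p = 0.00864, or 0.319 with an estimated correlation and 0.302 with each array centred on its median). They were led by the snoRNP protein Nop56 at −2.54 (SE 0.10), Nsa2 at −2.16 (SE 0.17), the polymerase subunit Polr1c at −1.80 (SE 0.14) and Nob1 at −1.58 (SE 0.14). Cytosolic chaperones (median −0.32, 13 of 35 lower, 6 higher, camera adjusted p = 0.0304, or 0.503 with an estimated correlation and 0.143 with centring) were lower too. Among them were the chaperonin subunits Tcp1 at −2.03 (SE 0.09) and Cct5 at −1.42 (SE 0.16) and Hspa8 at −1.58 (SE 0.13).

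In total 4513 genes differed between the pools of untransduced cells, 2148 higher and 2365 lower in the polysomal pool, with a median over all genes of −0.0894. Centring each array on its median shifts all genes alike, which moves this median to 0.722 and the count to 7164, of which 95.2% are higher, against 47.6% in the values as deposited. With all arrays quantile normalized the large-subunit median is −0.09 (camera adjusted p = 0.072) and Rpl11 and Rps18 turn positive, so the place of these mRNAs below the average gene depends on the scaling.

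The Rps19 shRNA changed the recruitment of 96 genes, 32 upward and 64 downward. Pigk, the catalytic subunit of the enzyme that attaches GPI anchors, rose from −0.89 ± 0.12 with the control construct to 0.61 ± 0.14 with the shRNA (2.82-fold, SE 0.20, adjusted p = 0.0294). Stt3a, the catalytic subunit of oligosaccharyltransferase, rose by 1.24 (SE 0.24), the protein palmitoyltransferase Zdhhc20 by 1.16 (SE 0.18), the peroxisomal carrier Slc25a17 by 1.13 (SE 0.17) and the phosphatase regulator Igbp1 by 1.40 (SE 0.19). The J-domain protein Dnajc17 rose by 1.90 (SE 0.30), and the dim mRNAs of gasdermin Gsdma and the progesterone receptor Paqr7 rose by 2.35 (SE 0.40) and 2.03 (SE 0.37). Adjusted p for these genes runs from 0.0294 to 0.0468.

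Among the losses, Siva1, a small pro-apoptotic protein induced by p53, fell by 1.51 (SE 0.24, adjusted p = 0.0307), from 0.48 ± 0.26 to −1.03 ± 0.06. The reductase Cyb5r4 fell by 1.38 (SE 0.13, adjusted p = 0.00868), the smallest adjusted p of those named for this shRNA. Lyrm2, of a family of small mitochondrial assembly proteins, fell by 1.17 (SE 0.20), the complex III assembly factor Uqcc2 by 1.16 (SE 0.19), and the iron-sulphur cluster factor Bola3 by 1.14 (SE 0.22). The mitochondrial ribosomal proteins Mrps24 and Mrps36 fell by 0.98 (SE 0.14) and 0.75 (SE 0.13), and the complex I subunit Ndufb9 by 0.66 (SE 0.13). The phosphatase inhibitor Ppp1r2 fell by 1.22 (SE 0.16), the start-codon selection factor Eif1b by 1.22 (SE 0.15), and Btbd6 by 1.17 (SE 0.18). The chromatin remodelling subunit Bcl7c fell by 1.16 (SE 0.23), the SMN complex subunit Gemin7 by 1.14 (SE 0.18) and the mitotic phosphatase Cdc25b by 1.05 (SE 0.16), with adjusted p of at most 0.0493. The respiratory supercomplex factor Cox7a2l rose by 1.04 (SE 0.17). The oxidative phosphorylation list had a median of 0.02 (1 rose and 1 fell of 74, camera adjusted p = 0.444). Mitochondrial ribosomal proteins had a median of −0.09 (0 rose and 2 fell of 76, camera adjusted p = 0.0617).

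Lists of ribosomal protein and other TOP mRNAs rose in recruitment with the Rps19 shRNA in camera, with few genes past the threshold. Large-subunit ribosomal protein mRNAs moved by a median of 0.39 (list median −1.16 ± 0.15 with the control construct, −0.78 ± 0.08 with the shRNA). Rpl37 and Rpl14 rose by 1.33 (SE 0.20, adjusted p = 0.03) and 1.17 (SE 0.22, adjusted p = 0.0444), 2 of 22 over all genes and 10 when adjusted over the list alone. Small-subunit mRNAs moved by a median of 0.37 (0 of 21 past the threshold, 8 over the list alone), with Rps25 at 1.17 (SE 0.28, adjusted p = 0.085) and Rps18 at 0.55 (SE 0.14, adjusted p = 0.0982). Other TOP mRNAs moved by 0.47 (0 of 19, 8 over the list alone), with Btf3 at 0.67 (SE 0.13, adjusted p = 0.0501) and Eif3h at 0.68 (SE 0.16, adjusted p = 0.0738). Camera gave adjusted p = 6.59e-07 (small), 1.4e-08 (large) and 1.46e-06 (TOP), and adjusted p = 0.458, 0.369 and 0.335 with an estimated correlation. The ratio of the highest polysomal to the highest subpolysomal signal of the gradient rose by 0.37 at the same time, and most of these probe sets lie near that maximum. Quantile normalization leaves camera adjusted p = 0.671, 0.365 and 0.267. The 19 ribosomal protein and TOP mRNAs below 0.4 of the maximum moved by a median of 0.53, above all brightness-matched random lists (percentile 100).

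Lists of protein turnover and cell growth rose beside them in camera. Proteasome mRNAs had a median of 0.29 (1 of 38 rose, 4 over the list alone, camera adjusted p = 1.46e-06, or 0.301 with an estimated correlation). Its core subunit Psmb1 rose by 0.78 (SE 0.14, adjusted p = 0.0418). Cytosolic chaperones had 0.27 (1 of 35, camera adjusted p = 3.84e-05, or 0.294 with an estimated correlation). The chaperonin subunit Tcp1 rose by 0.86 (SE 0.13, adjusted p = 0.03). Ribosome biogenesis had 0.15 (1 of 59, 2 over the list alone, camera adjusted p = 0.000796, or 0.294 with an estimated correlation). Polr1c, shared by RNA polymerases I and III, rose by 1.10 (SE 0.19, adjusted p = 0.0418). Initiation factors had 0.19 (0 rose and 1 fell of 30, camera adjusted p = 0.0119, or 0.15 with an estimated correlation). DNA replication had 0.18 (1 of 37, the clamp loader Rfc4 at 0.96, SE 0.18, camera adjusted p = 0.0119, or 0.636 with an estimated correlation). Cholesterol synthesis had 0.19 (0 of 20, camera adjusted p = 0.0136, or 0.294 with an estimated correlation). Erythroid membrane and haemoglobin mRNAs had 0.16 (0 of 21, camera adjusted p = 0.0103, or 0.15 with an estimated correlation), inside the range of −0.165 to 0.175 of most random lists of the same brightness (percentile 95.8). The control construct alone gave −0.11 for the proteasome and −0.10 for chaperones (camera adjusted p = 0.0186 and 0.124). Against untransduced cells the Rps19 shRNA raised them by only 0.178 and 0.0913. Camera adjusted p was 0.00354 and 0.0153, but 0.084 for DNA replication and 0.0587 for cholesterol synthesis. The lists of erythroid regulators (median −0.01), haem synthesis and iron (−0.07), p53 targets (−0.17), the integrated stress response (0.12), mitosis (0.07, Cdc25b its only member past the threshold), apoptosis regulators (−0.01), interferon response (0.06) and untranslated RNAs (−0.01) had camera adjusted p of 0.0979 or more.

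The count of 96 is fragile: leaving out any gradient of either group lowers it to between 0 and 3 genes, and fitting the Rps19 and control gradients alone or centring each array on its median gives 0.

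The 6 Rpl11 arrays differ from the other 18 in their median signal, and 5 of them in a control ratio. The log2 ratio of the 3' to the 5' Gapdh control probe sets was 0.99, 1.23 and 3.29 in the polysomal and −0.46, 2.10 and 3.89 in the subpolysomal pools of replicates 1 to 3, against −0.42 to 0.42 on all other arrays. For Actb it reached 1.35 and 1.96 against at most 0.98. Median signals were lower as well, 46.8 to 49.0 against 58.9 to 68.9 in polysomal and 65.7 to 86.7 against 97.2 or more in subpolysomal pools. A high 3' to 5' ratio is what fragmented RNA or short labelled copies give.

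**Figure D2:**
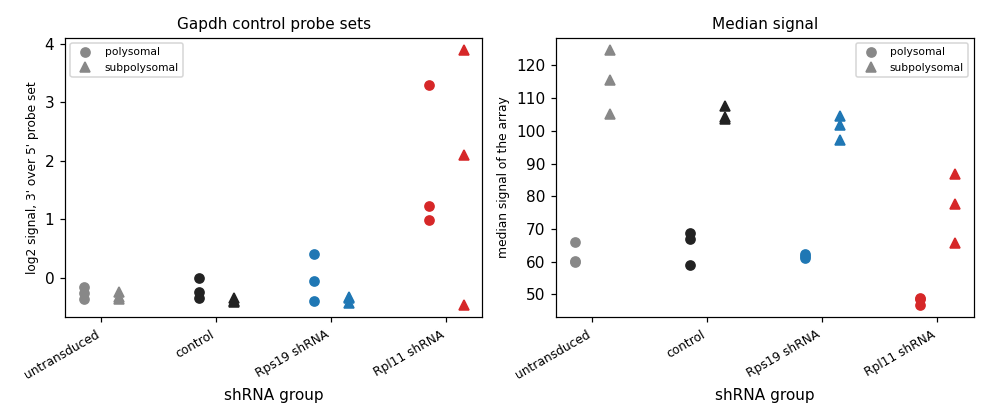
Log2 ratio of the 3' to the 5' Gapdh control probe sets and median signal of each of the 24 arrays, by shRNA group and fraction. The Gapdh ratio reaches 3.29 and 3.89 with the Rpl11 shRNA and stays between −0.42 and 0.42 elsewhere.

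With the Rpl11 shRNA the recruitment of the oxidative phosphorylation list fell. Of 74 nuclear-encoded oxidative phosphorylation mRNAs 26 fell in recruitment and 3 rose (37 and 7 over the list alone), with a median change of −0.42. The list medians were −0.01 ± 0.04 with the control construct and −0.33 ± 0.03 with the shRNA. The ATP synthase subunit Atp5md fell by 1.71 (SE 0.24), the complex I subunits Ndufc1, Ndufb3 and Ndufa1 by 1.22 (SE 0.16), 1.11 (SE 0.15) and 0.88 (SE 0.13). The electron carrier cytochrome c, Cycs, which is on the apoptosis list, fell by 0.73 (SE 0.12). Mitochondrial ribosomal proteins followed, 14 of 76 down and 1 up (30 and 5 over the list alone) with a median of −0.21. Mrpl42 fell by 1.21 (SE 0.16), Mrpl18 by 1.09 (SE 0.17), Mrpl51 by 0.97 (SE 0.15) and Mrps14 by 0.89 (SE 0.13). Adjusted p for these genes runs from 0.0087 to 0.0121. Camera gave adjusted p = 6.4e-09 for oxidative phosphorylation and 3.8e-05 for mitochondrial ribosomal proteins, and adjusted p = 0.165 and 0.326 with an estimated correlation. Most random lists of the same brightness had medians from −0.25 to 0.00293, and none reached this one. The median change of the list was −0.39, −0.41 and −0.48 in the 3 Rpl11 gradients. The Gapdh 3' to 5' ratio was higher in the polysomal pool of the first (difference 1.45) and higher in the subpolysomal pool of the others (differences −0.87 and −0.60), while that of Tfrc was higher in the polysomal pool of all 3 (0.679, 0.214 and 0.494).

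Untranslated RNAs moved further out of the polysomal pool as well. All 13 on the list were lower, with a median of −0.55 (2 past the threshold, 3 over the list alone, camera adjusted p = 0.00155, or 0.251 with an estimated correlation). Kcnq1ot1 fell by 2.29 (SE 0.45, adjusted p = 0.0181) and the snoRNA host Snhg5 by 0.77 (SE 0.18, adjusted p = 0.0388). Zfas1, another snoRNA host transcript, fell by 1.65 (SE 0.32). Outside that list survivin Birc5 fell by 0.64 (SE 0.13), Cdca3 by 0.77 (SE 0.15), cyclin G1, Ccng1, by 0.84 (SE 0.15) and the ribosomal protein paralogue Rps27l by 0.69 (SE 0.14). The snoRNP protein Nop10 fell by 0.86 (SE 0.14), the initiation factor Eif5a2 by 0.87 (SE 0.19) and glycophorin Gypc by 0.71 (SE 0.16). Among the largest losses, most of them of dim mRNAs, are the sulphotransferase Ust (−3.06, SE 0.79), Lrrc18 (−2.71, SE 0.55), the kinase subunit Prkar1b (−2.60, SE 0.60), the transcription factor Creb3l3 (−2.43, SE 0.62) and the adrenaline-forming enzyme Pnmt (−2.41, SE 0.61). Dip2a (−1.85, SE 0.43) and Mdga1 (−1.64, SE 0.42) belong to them too.

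Gains fell on the lists of cholesterol synthesis, chaperones, proteasome, DNA replication, other TOP mRNAs and ribosome biogenesis. The mevalonate enzyme Mvd rose by 1.43 (SE 0.25) and the sterol isomerase Ebp by 0.69 (SE 0.16). They are 2 of 20 cholesterol genes past the threshold and 9 over the list alone, with a median of 0.45 (camera adjusted p = 8.53e-05, or 0.128 with an estimated correlation). Chaperones had a median of 0.34 (4 of 35, 8 over the list alone, camera adjusted p = 0.000128, or 0.315 with an estimated correlation), and 0.113 against untransduced cells. Tcp1 (1.04, SE 0.13), Cct5 (0.86, SE 0.22), Cct6a (0.63, SE 0.14) and the kinase co-chaperone Cdc37 (0.92, SE 0.24) rose. Proteasome mRNAs had 0.33 (5 of 38, 12 over the list alone, camera adjusted p = 3.8e-05, or 0.326 with an estimated correlation), and 0.183 against untransduced cells. Psmc5 rose by 1.16 (SE 0.27) and Psma4 by 0.92 (SE 0.20). DNA replication had 0.33 (2 of 37, 6 over the list alone, camera adjusted p = 0.00112, or 0.39 with an estimated correlation). Mcm7 rose by 0.85 (SE 0.21) and thymidine kinase Tk1 by 0.56 (SE 0.14). Other TOP mRNAs moved by 0.35 (2 of 19, 5 over the list alone, camera adjusted p = 7.33e-05, or 0.381 with an estimated correlation), led by Eef1d (1.34, SE 0.20) and Eif3l (1.31, SE 0.20). Small- and large-subunit ribosomal protein mRNAs moved by 0.17 (0 rose and 1, Rps27l, fell of 21, camera adjusted p = 0.0715) and 0.14 (0 of 22, camera adjusted p = 0.0749). Ribosome biogenesis had 0.20 (4 rose and 1 fell of 59, 13 and 2 over the list alone, camera adjusted p = 0.00042, or 0.251 with an estimated correlation). The rRNA methyltransferase Fbl rose by 0.92 (SE 0.16), Noc4l by 0.98 (SE 0.19) and Rrp1 by 0.90 (SE 0.13).

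Single genes outside these lists rose more. Stt3a and Pigk rose by 1.52 (SE 0.24) and 1.44 (SE 0.20), close to their changes with the Rps19 shRNA, and the cytochrome oxidase assembly factor Sco2 by 1.69 (SE 0.22). The tetraspanin Cd37 rose by 1.74 (SE 0.41), and the dim mRNAs Tnip2, Cyb5d2, Ndrg4 and Rec8 by 2.60 (SE 0.42), 2.51 (SE 0.56), 2.08 (SE 0.47) and 1.53 (SE 0.28). The initiation factor subunits Eif3m, Eif2b2 and Eif2b5 rose by 1.06 (SE 0.19), 0.78 (SE 0.14) and 0.69 (SE 0.14). Their list did not reach the threshold (median 0.16, 3 rose and 1 fell of 30, camera adjusted p = 0.0649). Erythroid genes moved singly. The iron exporter Slc40a1 rose by 0.89 (SE 0.17), the blood group protein Rhd by 0.78 (SE 0.14), biliverdin reductase Blvrb by 0.66 (SE 0.13) and the master regulator Gata1 by 0.62 (SE 0.15, adjusted p = 0.0444). The lists of erythroid membrane (median 0.06), erythroid regulator (0.11) and haem and iron mRNAs (0.04) had camera adjusted p of 0.352 or more. The serine synthesis enzyme Psat1 (0.95, SE 0.19) and the seryl-tRNA synthetase Sars (0.98, SE 0.18) rose in the integrated stress response list (median 0.16, camera adjusted p = 0.1). The mitotic kinases Aurkb (0.95, SE 0.18) and Cdk1 (0.72, SE 0.14) rose in the mitosis list (median 0.09, 4 rose and 2 fell of 34, camera adjusted p = 0.197). The p53 targets (median −0.10, 0 rose and 2 fell of 25), apoptosis regulators (−0.13, 1 fell of 22) and interferon response genes (0.14, 0 of 22) had camera adjusted p of 0.326 or more.

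In all, 626 genes passed the threshold with the Rpl11 shRNA, 233 up and 393 down. The count drops to 133 without control replicate 1 and to 163 without Rpl11 replicate 3. It is 0 when Rpl11 replicates 2 and 3 are left out together or when only the Rpl11 and control gradients are fitted, and 166, of which 19.9% are higher against 37.2%, when each array is centred on its median.

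**Figure D3:**
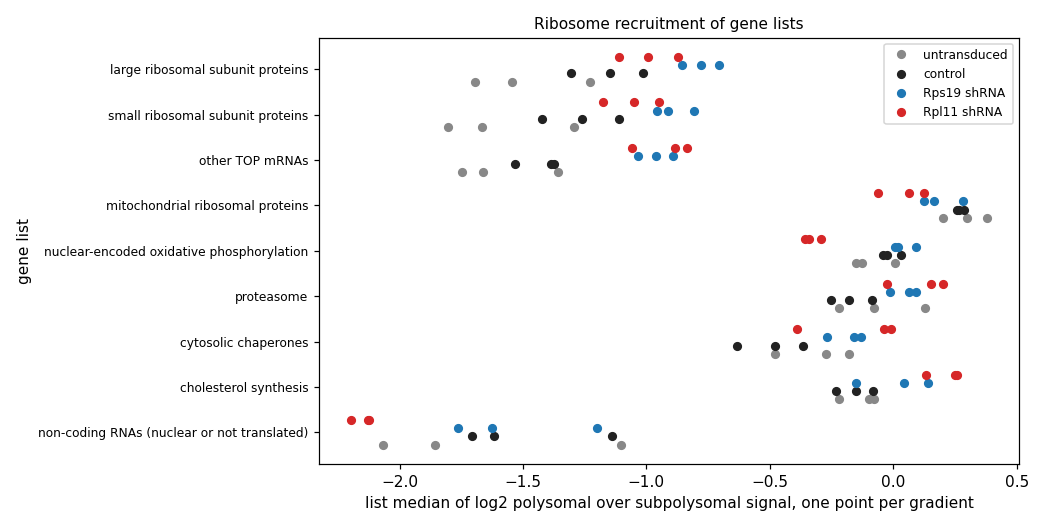
Median log2 polysomal over subpolysomal signal of 9 gene lists in each of the 12 gradients. Oxidative phosphorylation has −0.33 ± 0.03 with the Rpl11 shRNA and −0.01 ± 0.04 with the control construct (mean ± SD, n = 3).

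Against separate controls, part of the response was common to both shRNAs. Of the 96 genes called with the Rps19 shRNA, 86 moved the same way with the Rpl11 shRNA against untransduced cells. Of the 626 called with the Rpl11 shRNA, 527 moved the same way with the Rps19 shRNA against untransduced cells. Across 11035 genes, which are not independent replicates, the changes correlate at r = 0.196 with untransduced cells as the control of the Rpl11 shRNA and at 0.225 with them as the control of the Rps19 shRNA.

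Against the control construct, recruitment rose in both for 14 genes and fell in both for 28, and 94 of the 96 moved the same way. The shared control gradients alone can give this. Data simulated without any effect, with lists of these sizes taken from the smallest p, share 13.9 (6 to 22) and 28.6 (18 to 39) genes, and 88 (81 to 96) of 96 move the same way. Stt3a, Pigk, Slc25a17, Zdhhc20, Tcp1 and Polr1c are among the genes that rose in both, the last 4 by 1.08, 1.10, 1.04 and 0.87 with the Rpl11 shRNA. So did the signal peptide peptidase H13 (1.10 and 1.08 with the Rps19 and the Rpl11 shRNA), the coagulation inhibitor Tfpi (1.11 and 0.93) and the lysosomal peptidase Prcp (0.98 and 0.98). Lyrm2 (−1.17 and −1.19), Bola3 (−1.14 and −1.11), Uqcc2 (−1.16 and −0.84), Mrps24 (−0.98 and −0.76), Mrps36 (−0.75 and −0.79), the mitochondrial calcium uniporter subunit Smdt1 (−0.75 and −0.74), the mitochondrial phosphatase Ptpmt1 (−1.03 and −0.64) and the Myc-binding protein Mycbp (−1.07 and −1.35) fell in both. The changes against the shared control correlate at r = 0.557 (covariance 0.125), and simulated data give 0.5 (0.0752), at most 0.524 (0.0816). Leaving out a gradient gives r of 0.467 to 0.636, so an excess is not shown.

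**Figure D4:**
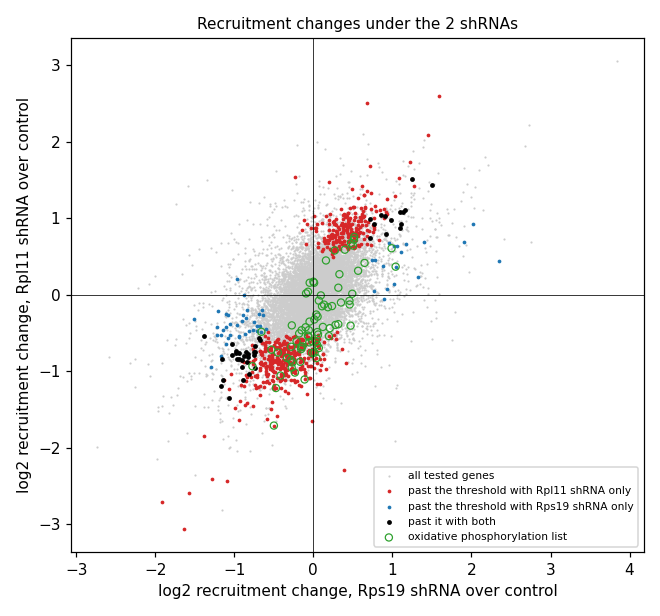
Recruitment change of each of 11035 genes with the Rps19 shRNA against that with the Rpl11 shRNA. The correlation is 0.557, or 0.467 to 0.636 with a gradient left out.

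The oxidative phosphorylation list also differed between the shRNAs. Compared directly, 39 of 74 oxidative phosphorylation mRNAs were higher with the Rps19 than with the Rpl11 shRNA when adjusted over the list alone, 6 over all genes and none lower. The median was 0.40 (camera adjusted p = 2.77e-17, or 0.0545 with an estimated correlation). Ndufb3 was higher by 1.00 (SE 0.15), the oxidase subunit Cox7a2 by 0.87 (SE 0.13), the ATP synthase subunits Atp5l and Atp5mpl by 0.76 (SE 0.13) and 0.77 (SE 0.14), and Cycs, of the apoptosis list, by 0.76 (SE 0.12). Mitochondrial ribosomal proteins were higher by 0.11 (3 of 76 past the threshold, 6 over the list alone, camera adjusted p = 0.00261, or 0.581 with an estimated correlation), through Mrpl18 (1.04, SE 0.17), Mrps14 (0.94, SE 0.13) and Mrpl51 (0.81, SE 0.15). Their median lies inside the brightness-matched range (−0.0516 to 0.128). All 13 untranslated RNAs were higher, by a median of 0.57 (1 past the threshold, 3 over the list alone, camera adjusted p = 7.55e-05, or 0.231 with an estimated correlation). Kcnq1ot1 was higher by 2.68 (SE 0.45), the proton pump subunit Atp6v1g1 by 1.29 (SE 0.12, adjusted p = 0.00646), the deadenylase Cnot6 by 1.38 (SE 0.21), the translation repressor Gigyf2 by 1.25 (SE 0.22) and the lectin Clec4e by 1.57 (SE 0.28). Lower with the Rps19 shRNA were Eif1b (−0.80, SE 0.15), Commd5 (−1.76, SE 0.23), the meiotic cohesin Rec8 (−1.77, SE 0.28), Tcl1b3 (−2.10, SE 0.38) and the dim mRNAs Igf2os (−3.01, SE 0.37) and Ceacam15 (−2.93, SE 0.54). Rpl37 was higher by 1.10 (SE 0.20, adjusted p = 0.0468), the only ribosomal protein gene past the threshold. The medians of small- and large-subunit mRNAs (0.20 and 0.26; camera adjusted p = 0.00282 and 0.000104; adjusted p = 0.759 and 0.581 with an estimated correlation) lie inside their brightness-matched ranges and turn to −0.07 and −0.04 once the trend over brightness is removed.

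These direct differences involve 61 genes, 48 higher and 13 lower with the Rps19 shRNA. All lists without a call in this contrast, from TOP mRNAs (median 0.02) to erythroid membrane mRNAs (0.28, camera adjusted p = 0.0614) and cholesterol synthesis (−0.21, camera adjusted p = 0.0501), had no more than 1 gene past the threshold. The count rises to 128 without Rpl11 replicate 1 and falls to 1 with replicates 2 and 3 left out or with each array centred on its median.

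Bag1, an Hsp70 co-chaperone whose mRNA carries an internal ribosome entry site, was named by the study from these same samples, so its values are no independent evidence. Its recruitment was 0.08 ± 0.12 in untransduced cells, 0.04 ± 0.14 with the control construct, −0.74 ± 0.08 with the Rps19 shRNA and −0.48 ± 0.32 with the Rpl11 shRNA. The changes of −0.78 (SE 0.17, adjusted p = 0.0663) and −0.51 (SE 0.17, adjusted p = 0.105) stay short of the threshold over 11035 genes. So does the difference between them (−0.26, SE 0.17, adjusted p = 0.498), in a contrast that called 0% of simulated log2 changes of 0.5. The 3 Rpl11 gradients read −0.84, −0.28 and −0.31. Its level stood at 0.01 (SE 0.14, adjusted p = 0.976) and −0.03 (SE 0.14, adjusted p = 0.885), the latter 0.37 with each array centred on its median. In the deposited polysomal shares Bag1 went from 0.506 ± 0.0242 with the control construct to 0.374 ± 0.0133 and 0.419 ± 0.0527 (n = 3 each), with 0.514 ± 0.0199 in untransduced cells. The list of 25 mRNAs with a reported internal ribosome entry site, Bag1 included, had medians of 0.08 with the Rps19 shRNA (camera adjusted p = 0.615, 0 past the threshold) and 0.30 with the Rpl11 shRNA (camera adjusted p = 0.122, 0 past the threshold). The other 24 had medians of 0.0933 and 0.307, and no test set Bag1 against them. Cdkn1b stood at 0.66 (SE 0.22, adjusted p = 0.179) in the first and Bcl2 at 0.92 (SE 0.28, adjusted p = 0.0821) in the second.

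In level, the lists of red cell products leaned down with the Rps19 shRNA, without a gene past the threshold. All but 3 of 25 haem synthesis and iron genes were lower (median −0.28; camera adjusted p = 0.000168, or 0.0382 with an estimated correlation), although none passed over all genes and 3 did over the list alone. Mitoferrin Slc25a37, which brings iron into mitochondria, stood 2.82-fold lower (SE 0.31, adjusted p = 0.0537), at 12.23 ± 0.08 against 13.73 ± 0.49 with the control construct. Haem oxygenase Hmox1 stood at −1.37 (SE 0.32, adjusted p = 0.086). Erythroid membrane and haemoglobin genes had a median of −0.43 (17 of 21 lower, 0 past the threshold, 3 over the list alone, camera adjusted p = 0.000168, or 0.294 with an estimated correlation). Ankyrin, Ank1, stood at −0.53 (SE 0.16, adjusted p = 0.149). Erythroid regulators had −0.21 (0 of 30, camera adjusted p = 0.0636), with Trim10 at −1.77 (SE 0.50, adjusted p = 0.137) and Foxo3 at −0.57 (SE 0.18, adjusted p = 0.157). Stress genes leaned down too. The integrated stress response list had −0.26 (1 of 29, camera adjusted p = 0.0024, or 0.294 with an estimated correlation), and its transcription factor Cebpb fell by 1.07 (SE 0.21, adjusted p = 0.049). The residuals of control and Rps19 gradients with the same number correlate in level (0.528, 0.294 and 0.21), and gradients fall into 2 sets that cross the groups. With the replicate number as a block, 0 genes of the haem, membrane and regulator lists pass, Cebpb falls short, and the camera adjusted p of erythroid regulators becomes 0.0431. With the sets, taken from these residuals, as a factor, 9 of 25 haem and iron and 9 of 21 erythroid membrane genes fell and none rose (camera adjusted p = 2.9e-05 and 7.46e-06). Of the regulators, 3 rose and 7 fell. In the same fit 2 of 5 mast cell and basophil genes rose (camera adjusted p = 0.142). Gadd45a, a p53 target, stood at −1.28 (SE 0.26, adjusted p = 0.0527) in a list that did not move (median −0.04, camera adjusted p = 0.129).

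**Figure D5:**
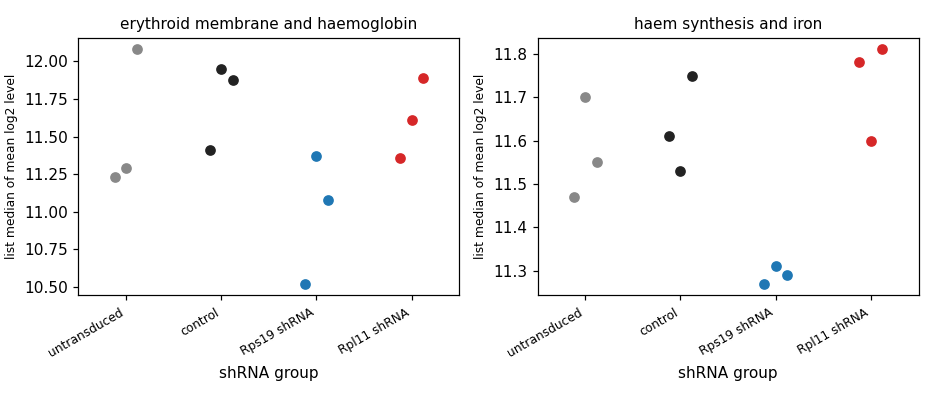
Median level of the erythroid membrane and haemoglobin list and of the haem synthesis and iron list in each gradient. With the Rps19 shRNA the gene changes have medians of −0.43 and −0.28 against the control construct.

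Besides Rps19 itself, other ribosomal protein mRNAs leaned lower in level with the Rps19 shRNA. Rps6 fell by 1.00 (SE 0.19, adjusted p = 0.0392), while Rpl14 stood at −1.19 (SE 0.32, adjusted p = 0.12). The TOP mRNAs Eif4b and Nap1l1 stood at −1.15 (SE 0.24, adjusted p = 0.0527) and −0.73 (SE 0.17, adjusted p = 0.093). The medians were −0.26 for the large subunit (0 of 22, camera adjusted p = 0.000222), −0.37 for TOP mRNAs (0 of 19, 4 over the list alone, camera adjusted p = 5.02e-05) and −0.18 for the small subunit (2 of 21, Rps19 itself and Rps6, camera adjusted p = 0.00108 with Rps19 in the list). With an estimated correlation these are adjusted p = 0.595, 0.521 and 0.654, and the last median lies inside its brightness-matched range (−0.187 to 0.0039) and turns to 0.01 under quantile normalization. Qars, the glutamine tRNA synthetase, fell by 1.55 (SE 0.20, adjusted p = 0.0121), Polr1c by 0.79 (SE 0.13), the mitochondrial ribosomal protein Mrpl1 by 0.76 (SE 0.14). The respiratory genes Cox7a2l and Ndufb8 fell by 1.03 (SE 0.16) and 0.87 (SE 0.14). With the replicate number as a block Qars and Cox7a2l stay past the threshold, and Rps6, Mrpl1, Polr1c and Ndufb8 do not. Oxidative phosphorylation had a median of −0.10 (2 of 74, camera adjusted p = 0.0233, or 0.674 with an estimated correlation), inside its brightness-matched range (−0.142 to −0.00915), and untranslated RNAs −0.37 (0 of 13, camera adjusted p = 0.0164, or 0.521 with an estimated correlation).

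Among the rising mRNAs, the translocon partner Sec63 rose by 1.13 (SE 0.18), its luminal J-domain relative Dnajc1 by 1.03 (SE 0.17) and the lysosomal sorting enzyme Gnptg by 1.45 (SE 0.28, adjusted p = 0.0477). The oligosaccharyltransferase subunit Rpn2 rose by 1.05 (SE 0.17), from 11.43 ± 0.24 to 12.48 ± 0.17. The retinol saturase Retsat rose by 1.13 (SE 0.20), the actin regulator Nckap1 by 1.13 (SE 0.18), and calcineurin Ppp3ca by 1.08 (SE 0.17). The VCP methyltransferase Vcpkmt rose by 1.03 (SE 0.16), the sialyltransferase St8sia4 by 1.26 (SE 0.23) and Lrrn3 by 1.30 (SE 0.25). Losses outside the lists include the erythroid mitochondrial protein Fam210b (−1.54, SE 0.30, adjusted p = 0.0477), Nxpe2 (−1.91, SE 0.36), and Rp2 (−1.45, SE 0.18). The dim mRNAs of casein Csn1s2a (−2.37, SE 0.35), Fam131a (−1.91, SE 0.20), Gsdma (−1.87, SE 0.19), Pou2f3 (−1.62, SE 0.27) and Afmid (−1.42, SE 0.26) fell as well. In total 89 genes changed in level, 37 up and 52 down. This count falls to between 3 and 14 when a gradient is left out to 6 when only the groups compared are fitted and to 17, of which 2 are higher, with the replicate number as a block. It rises to 1444 when 2 sets of gradients seen in the residuals are fitted as a factor. Initiation factors (median −0.08), mitochondrial ribosomal proteins (0.01), ribosome biogenesis (0.14), proteasome (0.16), chaperones (−0.02), DNA replication (0.00), mitosis (0.00), apoptosis (−0.13), cholesterol synthesis (−0.03), interferon response (−0.15) and mRNAs with an internal ribosome entry site (0.01) had camera adjusted p of 0.0636 or more.

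In level, the Rpl11 shRNA raised the proteasome and chaperone lists, on arrays of which 5 of 6 have high 3' to 5' ratios. Proteasome mRNAs were higher by a median of 0.32 (13 of 38 rose, none fell, camera adjusted p = 3.6e-06, or 0.465 with an estimated correlation). Psmc4 rose by 1.51 (SE 0.24), Psmd12 by 1.22 (SE 0.18), Psmc3 by 0.98 (SE 0.15) and Psmc2 by 0.86 (SE 0.15). Chaperones had a median of 0.21 (11 of 35 rose, camera adjusted p = 0.0151, or 0.685 with an estimated correlation). The stress-induced Hspa1b rose by 2.24 (SE 0.53), from 7.69 ± 0.51 to 9.93 ± 1.29. Dnaja1 rose by 1.18 (SE 0.23), Dnajb4 by 0.84 (SE 0.16) and, outside this list, the endoplasmic reticulum chaperone Hspa5 by 1.32 (SE 0.20). Mitochondrial ribosomal proteins had 0.16 (11 of 76 rose, camera adjusted p = 0.000538, or 0.685 with an estimated correlation), with Mrpl1 up by 1.24 (SE 0.14) and Mrps22 by 1.13 (SE 0.15). Oxidative phosphorylation had 0.05 (14 rose and 4 fell of 74, camera adjusted p = 0.0132, or 0.685 with an estimated correlation). Ndufv1 rose by 0.99 (SE 0.17) and Ndufa5 by 0.90 (SE 0.12). Both mitochondrial medians lie inside their brightness-matched ranges (−0.0831 to 0.178 and −0.16 to 0.0566). Cholesterol enzymes rose singly, Cyp51 by 1.60 (SE 0.26) and Hmgcs1 by 1.52 (SE 0.38), in a list with a median of 0.21 (5 rose and 1 fell of 20, camera adjusted p = 0.0773).

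Single mitotic and interferon genes rose as well, Cdc20 by 1.21 (SE 0.14, adjusted p = 0.00148), Cdca8 by 0.99 (SE 0.16), and Ifi35 by 1.42 (SE 0.18), in lists with camera adjusted p = 0.126 and 0.0848. Red cell genes went both ways. The actin-capping protein Tmod1 rose by 1.83 (SE 0.37), glycophorin Gypc by 0.78 (SE 0.22), Rhd by 0.66 (SE 0.17), Rhag by 0.64 (SE 0.18), Flvcr1 by 0.82 (SE 0.16) and Urod by 0.59 (SE 0.14). The erythropoietin receptor Epor fell by 0.99 (SE 0.23), Id1 by 1.54 (SE 0.37), the cell-cycle repressor E2f4 by 2.19 (SE 0.32) and Hmox1 by 1.63 (SE 0.32). Erythroid membrane (median −0.13; 4 rose of 21), erythroid regulator (−0.36; 1 rose and 5 fell of 30) and haem and iron lists (−0.24; 3 rose and 2 fell of 25) had camera adjusted p of 0.0773 or more. The cytokine brake Socs1 fell by 3.11 (SE 0.41), and the demethylase Kdm6b fell by 2.62 (SE 0.58). The centromere protein Cenpb changed by −4.03 (SE 0.63), and the transcription factors Maff and Cited4 by −2.91 (SE 0.45) and −2.92 (SE 0.67). The death genes Bak1 and Bcl2l11 fell by 1.34 (SE 0.34) and 1.04 (SE 0.17). The p53 targets Phlda3, Pidd1 and Sertad1 fell by 1.05 (SE 0.22), 0.83 (SE 0.20) and 0.64 (SE 0.15). Their list had a median of −0.19 (0 rose and 3 fell of 25, camera adjusted p = 0.407). No rise is seen, in cells of unstated p53 status. Other large rises are Cd200r1 (2.24, SE 0.54), P2ry1 (2.07, SE 0.47), Tnfrsf13c (2.07, SE 0.62), Morrbid (2.05, SE 0.49), Itm2a (2.00, SE 0.31) and Zfp931 (1.96, SE 0.24). The largest losses also include Nxpe4 (−3.15, SE 0.42) and Mir1949 (−3.15, SE 0.61).

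In the values as deposited, ribosomal protein mRNAs were lower in level with the Rpl11 shRNA, against the same control gradients as with the Rps19 shRNA. Besides Rpl11 and Rps19, Rps6 fell by 0.83 (SE 0.19), Rps25 by 0.49 (SE 0.15), Fau by 0.48 (SE 0.15), Rpl41 by 0.49 (SE 0.16) and Rpl12 by 0.62 (SE 0.19). Among the other TOP mRNAs Eef2 fell by 1.00 (SE 0.21), Eif4b by 0.92 (SE 0.24) and Eef1d by 0.64 (SE 0.17), while vimentin, Vim, rose by 1.72 (SE 0.29). All 22 large-subunit genes were lower (median −0.40, 3 past the threshold; camera adjusted p = 0.000538, or 0.685 with an estimated correlation). Small-subunit genes (median −0.35, 5 of 21, camera adjusted p = 0.00256, or 0.685 with an estimated correlation) and TOP mRNAs (−0.40, 3 of 19, camera adjusted p = 0.0319, or 0.685 with an estimated correlation) have camera adjusted p = 0.084 and 0.117 with each array centred on its median. Single genes fell in lists without a call: Eif5a by 0.73 (SE 0.14), the polymerase I factor Ubtf by 0.94 (SE 0.25), Chac1 by 0.93 (SE 0.21), Atf5 by 0.86 (SE 0.23) and Dnmt1 by 0.99 (SE 0.23). The host transcript Snhg12 and the cell-cycle inhibitor Cdkn1b fell by 1.93 (SE 0.39) and 1.37 (SE 0.25). Their lists are initiation factors (median 0.05, 1 rose and 4 fell of 30), ribosome biogenesis (−0.01, 7 rose and 2 fell of 59), integrated stress response (0.06, 3 rose and 6 fell of 29), DNA replication (−0.03, 5 rose and 3 fell of 37), untranslated RNAs (−0.34, 3 fell of 13) and mRNAs with an internal ribosome entry site (−0.12, 2 rose and 5 fell of 25). With apoptosis regulators (−0.15, 1 rose and 3 fell of 22), they had camera adjusted p of 0.324 or more. In total 2231 genes changed in level, 963 up and 1268 down, with a median over all genes of −0.0793. Centring each array shifts all genes alike, which moves that median to 0.321 and the count to 3667, of which 89.6% are higher against 43.2%. Of the 2231 genes 1344 stay past the threshold. Leaving out a gradient gives 1081 to 3595.

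Compared directly in level, lists of red cell products, interferon response, chaperones, proteasome and mitochondria were lower with the Rps19 than with the Rpl11 shRNA. Protein 4.2, Epb42, was lower by 2.54 (SE 0.49), Tmod1 by 2.59 (SE 0.37), the adult globin Hbb-b2 by 1.67 (SE 0.43), glycophorin Gypc by 1.03 (SE 0.22), Urod by 1.01 (SE 0.14), Slc25a37 by 1.19 (SE 0.31) and Slc40a1 by 0.96 (SE 0.24). The erythroid membrane list had a median of −0.44 (5 of 21 lower, camera adjusted p = 0.00267, or 0.355 with an estimated correlation). Haem and iron genes had −0.29 (7 of 25, camera adjusted p = 0.0463, or 0.314 with an estimated correlation). Interferon response genes had −0.48 (7 of 22, camera adjusted p = 0.00183, or 0.115 with an estimated correlation), with Ifi35 lower by 1.28 (SE 0.17) and the RNA-sensing kinase Eif2ak2 by 1.07 (SE 0.23). Chaperones had −0.27 (11 of 35, camera adjusted p = 0.000953, or 0.355 with an estimated correlation), with Hspa1b lower by 2.96 (SE 0.53) and Hsph1 by 0.99 (SE 0.22). The proteasome had −0.34 (7 of 38, camera adjusted p = 0.000185, or 0.355 with an estimated correlation), with Psmd12 lower by 1.28 (SE 0.18). Oxidative phosphorylation had −0.21 (11 of 74, camera adjusted p = 2.11e-05, or 0.635 with an estimated correlation), with Ndufb8 lower by 1.00 (SE 0.14). Mitochondrial ribosomal proteins had −0.13 (11 of 76, camera adjusted p = 0.00092, or 0.635 with an estimated correlation), with Mrpl1 lower by 2.00 (SE 0.14, adjusted p = 0.000144). The median of this last list lies inside the brightness-matched range of −0.148 to 0.112.

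Erythroid regulators went both ways (7 higher and 1 lower of 30, median 0.03, camera adjusted p = 0.749). Of genes higher with the Rps19 shRNA, the progenitor factor Gata2 was higher by 1.35 (SE 0.26), Myc by 1.16 (SE 0.23), Epor by 1.25 (SE 0.23), E2f4 by 2.00 (SE 0.32) and Spi1 by 0.96 (SE 0.22). So were the LIM-domain cofactor Ldb1 by 2.99 (SE 0.71), Cited4 by 2.85 (SE 0.67), Slc45a3 by 2.81 (SE 0.33), Cenpb by 3.37 (SE 0.63) and Mir1949 by 3.04 (SE 0.61). Lower were Gsta4 (−3.00, SE 0.59), Tnfrsf13c (−2.91, SE 0.62), the autophagy gene Trp53inp2 (−2.56, SE 0.48), the p53 targets Trp53inp1 (−1.39, SE 0.28) and Zmat3 (−0.77, SE 0.17) and the stress genes Aars (−1.25, SE 0.21) and Nupr1 (−1.75, SE 0.37). Each target returned in its own direction, Rpl11 higher by 2.33 (SE 0.25) and Rps19 lower by 0.96 (SE 0.16). Of 2258 genes 1309 were higher and 949 lower, and the 6 Rpl11 arrays, 5 of them with high 3' to 5' ratios, form one side of this contrast. Centring each array moves the median over all genes from 0.0918 to −0.252 and the share that is higher from 58.0% to 14.9%, while leaving out a gradient gives counts of 1182 to 3497.

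The control construct by itself moved no gene past the threshold. Against untransduced cells limma called 0 genes in recruitment (497 at p below 0.05 without adjustment) and 0 in level (260 at p below 0.05 without adjustment). The smallest p in recruitment belong to Slc35e3 (−1.10, SE 0.20, adjusted p = 0.981), Tchp (−1.77, SE 0.37, adjusted p = 0.994) and Poln (2.30, SE 0.49, adjusted p = 0.994). In level they belong to Tubb4a (−1.37, SE 0.27, adjusted p = 1) and Smim6 (0.96, SE 0.21, adjusted p = 1). As lists, small- and large-subunit ribosomal protein and TOP mRNAs were higher in recruitment by 0.30, 0.36 and 0.26 (camera adjusted p = 2.07e-08, 1.07e-08 and 7.87e-05, or adjusted p = 0.817 each with an estimated correlation), which for the ribosomal proteins is close to their change with the Rps19 shRNA. The small-subunit median turns to −0.03 under quantile normalization. Rps2 stood at 0.47 (SE 0.15), Rpl41 at 0.47 (SE 0.16), Tpt1 at 0.50 (SE 0.15) and Eef1a1 at 0.51 (SE 0.16), all with adjusted p = 0.994. Proteasome mRNAs were lower by 0.11 (camera adjusted p = 0.0186, or 0.819 with an estimated correlation). In level, erythroid membrane genes were higher by 0.18 (camera adjusted p = 0.0159, or 0.586 with an estimated correlation), with Epb42 at 0.84 (SE 0.49, adjusted p = 1). Cholesterol synthesis was lower by 0.12 (camera adjusted p = 0.0363, or 0.586 with an estimated correlation) and mitochondrial ribosomal proteins lower by 0.05 (camera adjusted p = 0.0363, or 0.919 with an estimated correlation).

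No marker list of other blood and stromal cells had a camera adjusted p below 0.05 in any comparison. In the direct comparison of levels, however, all 3 lymphocyte genes were higher with the Rps19 than with the Rpl11 shRNA (median 1.07, 1 past the threshold, camera adjusted p = 0.167, percentile 99.6 of brightness-matched lists). All 5 fibroblast and endothelial genes were higher too (median 0.81, 1 past the threshold, camera adjusted p = 0.128, percentile 99). Against the control construct the lowest were those of granulocyte and macrophage genes in level, with medians of −0.26 (0 of 7, camera adjusted p = 0.0636, or 0.0449 with the replicate number as a block) with the Rps19 and −0.57 (2 of 7 fell, camera adjusted p = 0.055) with the Rpl11 shRNA, where Spi1 fell by 1.03 (SE 0.22). Megakaryocyte genes had medians of −0.15 and −0.29 (camera adjusted p = 0.428 and 0.985), although Fli1 rose by 1.32 (SE 0.27) and Gp9 fell by 1.37 (SE 0.28) with the Rpl11 shRNA. Mast cell and basophil genes had 0.39 and −0.33 (camera adjusted p = 0.457 and 0.937), and lymphocyte genes 0.29 and −0.44 (camera adjusted p = 0.412 and 0.407). With the Rps19 shRNA these 2 lists lie at percentiles 98.5 and 97 of brightness-matched lists. Stem and early progenitor genes had 0.22 and 0.13 (camera adjusted p = 0.453 and 0.832) and fibroblast and endothelial genes 0.25 and −0.42 (camera adjusted p = 0.412 and 0.324). Replication-dependent histones and mitochondrially encoded transcripts have no tested gene.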

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

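All explanations weighed in this part were chosen after the results were seen, and the tests of the ceiling, the TOP change, the brightness trend, the unequal RNA quality of the pools and the separate batch were also written after their values were known.

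The difference between the groups is what marks the first set. In recruitment 61 genes differ between the Rps19 and the Rpl11 shRNA in limma: Kcnq1ot1 (2.68), Clec4e (1.57), Cnot6 (1.38), Atp6v1g1 (1.29) and Gigyf2 (1.25) have the largest positive values, and Igf2os (−3.01), Ceacam15 (−2.93), Tcl1b3 (−2.10), Rec8 (−1.77) and Commd5 (−1.76) the largest negative values. In level 2258 genes differ, with Cenpb (3.37), Mir1949 (3.04), Ldb1 (2.99), Cited4 (2.85) and Slc45a3 (2.81) at the upper and Gsta4 (−3.00), Hspa1b (−2.96), Tnfrsf13c (−2.91), Tmod1 (−2.59) and Trp53inp2 (−2.56) at the lower end. Of the 10 ways to split the 6 gradients, 1 reaches these counts in each measure, the real split itself, and the highest other split calls 3 and 0 genes.

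A signal in control probe sets outside the comparisons marks the second set. With the Rpl11 shRNA the log2 3' to 5' ratio of Gapdh is above every array of the other groups in polysomal replicates 1 to 3 (0.99, 1.23 and 3.29) and subpolysomal replicates 2 and 3 (2.10 and 3.89). That of Actb is above them in polysomal replicates 2 and 3 (0.94 and 1.35) and subpolysomal replicates 2 and 3 (1.57 and 1.96), each within its fraction. The 18S signal of subpolysomal replicate 1 is 11.68 in log2, against 8.07 to 9.97 in the other groups, while subpolysomal replicates 2 and 3 lie below that range at 6.97 and 7.065.

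How far does RNA quality explain the level changes with the Rpl11 shRNA? For genes with at least 2 probe sets (5074), the median absolute difference between the changes of the 2 brightest probe sets is 0.376 with the Rpl11 shRNA and 0.163 with the Rps19 shRNA, a ratio of 2.31, above the ratio of 1.60 between the SDs of all changes. This is in line with a 3' bias that moves probe sets of a gene apart. Replicate 1, with the lowest ratios, changes like replicates 2 and 3 across the 2231 called genes (r = 0.814, 98.1% of the same sign), but these genes were called from the mean of all 3 replicates, which favours agreement, and over all genes r is 0.453. The bound set for this r also presumed a clean replicate 1, and its polysomal Gapdh ratio of 0.99 is raised as well, so the question stays open. All 6 Rpl11 arrays have a lower median signal than any other array of their fraction, and whether they were run as a separate batch is not in the labels.

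Does the higher recruitment of ribosomal protein mRNAs with the Rps19 shRNA reflect translation or the top of the signal range? Across 12 gradients their median recruitment follows the log2 ratio of the highest signals of the 2 arrays with r = 0.985 (permutation p = 1e-05, the smallest possible, rho = 0.972), with r = 0.957 without the 2 farthest gradients and r = 0.938 within groups. With the Rps19 shRNA the median moves by 0.36 and the ratio of maxima by 0.37, and with the Rpl11 shRNA by 0.15 and 0.18. The highest signal of all 24 arrays is itself a ribosomal protein probe set, so this r cannot separate a ceiling from a change in recruitment, and for these bright probe sets the cause stays open. Among 19 ribosomal protein and TOP genes below the ceiling the median is 0.53 with the Rps19 shRNA (percentile 100 of brightness-matched lists) and 0.32 with the Rpl11 shRNA (percentile 99.89), which is consistent with better recruitment of TOP mRNAs beyond any ceiling.

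Is the lower recruitment of respiratory chain mRNAs with the Rpl11 shRNA technical? Brightness does not explain it, since the list median of −0.42 lies at percentile 0 of brightness-matched lists. Unequal RNA quality of the pools stays open. The median is −0.386 or lower in each Rpl11 gradient, but only replicate 1 has the higher Gapdh ratio in its polysomal pool, and the Tfrc ratio is higher in the polysomal pool of all 3 (0.679, 0.214 and 0.494). A length effect stays possible, since other mRNAs for short proteins fell as well (percentile 0). The lists of ribosomal proteins, many also short, did not fall.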

How the results depend on the processing

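Chosen after the data were seen were the brightness trend, the ceiling, the 2 sets of gradients, the larger set alone, Rpl11 replicates 2 and 3 left out, the block and the set for lists in level and untransduced cells as the control of lists, and all others were planned. Of the values for named genes under an alternative, 5183 kept their direction and their side of the threshold, 1666 lost the threshold, 53 gained it and 17 reversed. For gene lists 190 of the camera results kept their side, 123 lost it, 6 gained it and 4 reversed.

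Counts depend on the processing far more. In recruitment the 96 genes of Rps19 against the control construct become 1 with unpaired arrays, 0 with the replicate block, 0 with only the groups compared, 0 with median scaling, 0 without a filter, 258 with the stricter filter, 1 with all probe sets, 306 at a threshold of 0.10, 0 with the set of gradients as a factor, 0 in the larger set alone and 0 to 3 when a gradient is left out. The 626 of Rpl11 become, in the same order as far as they moved, 70, 335, 0, 166, 95, 1074 with the stricter filter, 1274 at 0.10, 0 without replicates 2 and 3 and 133 (without control replicate 1) to 601, with 163 without Rpl11 replicate 3. The 61 between the shRNAs become 3, 0, 0, 1, 15 and 13 under quantile normalization over all arrays and within fraction, 98 with a pseudocount of 39.258, 0 without a filter, 185 with the stricter filter, 10 with all probe sets, 207 at 0.10, 10 with the brightness trend removed, 38 without genes near the ceiling, 1 without Rpl11 replicates 2 and 3 and 0 to 128 (without Rpl11 replicate 1). The 0 of the control construct become 1 without a filter and 0 to 3 when a gradient is left out.

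In level the 89 of Rps19 become 952 unpaired, 17 with the block, 6, 57 with median scaling, 7 without a filter, 146 with trend and robust, 234 at 0.10, 1444 with the set as a factor, 0 in the larger set and 3 to 14 when a gradient is left out. The 2231 of Rpl11 become 4064 unpaired, 612 with only the groups compared, 3667 with median scaling (89.6% higher, against 43.2%), 1342 without a filter, 4307 with all probe sets, 3397 at 0.10, 716 without replicates 2 and 3 and 1081 to 3595 (without Rpl11 replicate 1). The 2258 between the shRNAs become 3945, 934, 1430 without a filter, 4307 with all probe sets, 987 without Rpl11 replicates 2 and 3 and 1182 to 3497. The 0 of the control construct become 0 to 1. Between the pools, 4513 become 2858 unpaired, 7164 with median scaling, 7707 with all probe sets and 3050 to 3893. The correlation of 0.557 becomes 0.196 and 0.225 with separate controls and 0.467 to 0.636 when a gradient is left out. Fewer gradients and fewer or more genes lie behind the alternatives that change them, and for the others the cause was not tested.

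Reversals concern targets, Bag1 and ribosomal proteins. Recruitment of Rps19 under its own shRNA is −0.93 with quantile normalization, −0.109 with it within fraction and −0.0388 with the trend removed, and under the Rpl11 shRNA −0.32, −0.0874 and, without control replicate 1 and Rpl11 replicate 1, −0.0151 and −0.0391 (up to 0.198 when another gradient is left out). That of Rpl11 under its own shRNA is −0.92 with quantile normalization, and its polysomal over subpolysomal value is 0.22, that of Rps18 0.0339. Bag1 recruitment between the shRNAs is 0.10 without Rpl11 replicates 2 and 3. Its level is −0.0711, −0.0142 and −0.0342 without control replicate 1, Rps19 replicate 2 and Rps19 replicate 3 (up to 0.0901), and with the Rpl11 shRNA 0.37 with median scaling and 0.0317 and 0.0306 without control replicate 2 and Rpl11 replicate 1 (down to −0.117). The second Rps19 probe set reads 0.16. Ribosomal protein lists turn between the shRNAs with the trend removed (camera adjusted p = 0.136 small, 0.783 large) and, for the control construct, the small subunit turns under quantile normalization (adjusted p = 0.962, within fraction 0.968). The cause was not tested.

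The replicate number as a block was tried although residuals share more than 0.1 in only 7 of 18 pairs in level (3 of them between the control construct and the Rps19 shRNA) and 0 of 18 in recruitment, and its counts of 0, 335 and 17 come with fewer residual degrees of freedom. Where a replicate is left out, the remaining pair carries the group, and with Rpl11 replicates 2 and 3 out the lone gradient is assumed to vary like the other groups. Signal over background limits the rest, since probe sets whose mean log2 signal lies below the median were not tested.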

Other observations

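The lists of short, long and selenoprotein mRNAs were chosen after the fall of respiratory chain mRNAs was seen, while their predictions were written before their values were computed, and the test against untransduced cells was added after the values against the control construct were seen.

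With the Rpl11 shRNA, short proteins lost polysomal mRNA well beyond mitochondria. The anaphase-promoting complex subunit Anapc13 stood at −1.13, prefoldin Pfdn4 at −1.12, the basal transcription factor subunit Gtf2a2 at −1.05, the dynein light chain Dynlrb1 at −1.04, the annexin partner S100a10 at −0.99, the actin-binding peptide Tmsb10 at −0.96, the oligosaccharyltransferase subunit Ost4 at −0.89 and the spliceosomal Lsm8 at −0.87. Of 49 such genes, gathered from families of small proteins outside mitochondria, 46 were lower and 26 fell past the threshold, none rose, and the median was −0.58.

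The hypothesis behind that list is that scarce large subunits thin out ribosomes on all mRNAs, so that a short coding sequence, which holds few ribosomes, drops out of the polysomal pool first, and with it the respiratory chain, whose proteins are short. The short-protein list lay at percentile 0 of brightness-matched lists (medians mostly −0.30 to 0.03), as predicted. Ribosomal proteins, many also short, are not on it, and their lists did not fall (medians 0.17 and 0.14). With the Rps19 shRNA the same list had a median of −0.17 (percentile 0.12, 33 of 49 lower, 1 fell). Shared control gradients could carry such a fall from one comparison to the other, but against untransduced cells the list lay at −0.136 with the Rps19 shRNA as well (percentile 0.19). The control construct by itself moved it up by 0.0888 (percentile 99.42, beyond most random lists), so falls of this size are not far from what a construct alone gives. The reverse was not found: 54 mRNAs for long proteins had a median of 0.01 at percentile 26.16 with the Rpl11 shRNA, and none passed the threshold. A selective effect on mRNAs for selenoproteins, tested on 14 genes, is not seen either (median −0.21, percentile 10.12, 1 rose and 3 fell). Unequal degradation of the RNA of the pools could also move short mRNAs, and this stays open. The short-protein list lay at −0.711, −0.504 and −0.616 and the respiratory list at −0.386 or below in the 3 Rpl11 gradients, of which only replicate 1 has the higher Gapdh ratio in its polysomal pool. Lengths of coding sequences were not available, so the lists rest on known protein sizes and a continuous relation was not tested.

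Other splits of the samples are too few for a share under 0.05. In recruitment 1 of 10 splits reaches the count of Rps19 against the control construct (highest other 0) and 1 of 10 that of Rpl11 (highest other 1). In level these are 1 of 10 (highest other 0) and 1 of 10 (highest other 1), and between the pools of untransduced cells 1 of 4 sign patterns (highest other 1). For the control construct against untransduced cells all 10 of 10 splits reach the count of 0 in each measure, but in level another split calls 654 genes. That split sets untransduced replicates 1 and 2 and control replicate 1 against the rest, which points to a structure of the samples that the labels do not name. The same division appears in the residuals of the level values, whose first component holds 52.5% of the variance and puts Rps19 replicate 1 with these gradients.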
